A study of Homo sapiens with 4 samples.

How the data were processed

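Total RNA was extracted from 4 cell lines, DLD1 and its derivatives SA, SPH and METS, and sequenced on libraries made with a standard Illumina protocol, per the labels' protocols. All lines were kept in the same medium with serum, per the labels' protocols. The authors deposited 1 table with a value per gene and line, rounded to 2 decimals. The deposited values were read as RPKM, reads scaled to the length of the gene model and to library size, from the values themselves, because they are not whole, their column sums differ between lines (from 275639 to 284919), and value times gene length in kb summed to between 913210 and 924096 per line over 34023 genes with a matched name. Whether reads or fragments were counted, the aligner, the counting tool and the annotation are not given in the sources used here. The genome build was hg19, per the submitters' processing notes. Small RNAs and some long RNAs are listed at 0 in all lines, so an entry of 0 was read only as listed at 0. Whether counting used strand is not stated, and overlapping genes cannot be told apart.

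The depth of a library was estimated from its low values. In RPKM a gene of known length takes values in steps worth 1 read, and the common step of genes of 200 to 500 bases (exon lengths from GENCODE 29) was found as the period with the highest score. At 1 RPKM a gene of 1 kb then held 53.7 reads in DLD1 (SD 0.36 over 200 bootstrap draws) and 53.1 in SPH (SD 0.35). For SA and METS the estimates were 49.3 and 51.4 reads, but with bootstrap SDs of 22.6 and 8.30, so their depth is poorly known. Depth sets counting error alone, and the spread between replicate cultures of a line is unknown because each line has 1 library. Mitochondrially encoded transcripts held 25.5% to 26.6% of the summed values in the 4 lines, and no 2 libraries held identical columns.

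Values were used as deposited, as log2(RPKM + 1). Genes entered a comparison where the higher library reached 1 RPKM, and were counted by a fixed rule of at least 4-fold. The classes named in the labels were compared with limma-trend (limma 3.58.1, R 4.3.3) and Benjamini-Hochberg adjustment, over genes of at least 1 RPKM in at least 2 of 4 libraries, 2 lines per class. The other 2 ways of splitting 4 libraries into pairs gave 0 and 0 genes past adjusted p 0.05 (limma-trend), with 325 and 330 at an unadjusted p under 0.05 against 974 for the labelled classes. The 3 possible splits are too few for a share under 0.05. The class test was also run on simulated values for 11262 genes, 200 of them changed, with the same spread of 0.2 (log2) between lines for every gene. It recovered 91 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 12 false calls. In the data the spread differs between genes (SE of the class fold 0.11 for VIM and 1.62 for H19). The simulated rates therefore do not give the power of the test on the data.

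For 34 gene lists the median log2 fold was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and is not a test. A list needed at least 5 genes of at least 1 RPKM, and 7 lists, among them the 6 lists of markers of other cell types, had fewer and are given as values. Gene names were matched to older symbols through the RefSeq table of GCF_000001405.40 (GRCh38.p14). Because that build differs from the authors' build, no coordinates are given, and the table was used only for names, chromosomes and neighbouring genes.

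The lists, thresholds and the rule for named genes were fixed before the data were examined. The rule took the 8 highest and 8 lowest folds of SA, SPH and METS against DLD1, the 12 highest and 12 lowest genes by the smallest fold over the 4 pairs of the class comparison, up to 8 genes in each direction apart in METS from all other lines, up to 4 members per list by class fold, and 12 genes named in advance. Names of clone type, ribosomal, small and mitochondrial RNAs were skipped in the ranked parts. Alternatives were a pseudocount of 0.1 or 5, no filter or a minimum of 5 RPKM, median-of-ratios factors, 2-fold and 8-fold rules, limma without trend and leaving out each library. A correction for GC content (lowess, span 0.3, transcript GC content from GENCODE 29) was added after seeing the data. Analyses used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. A few genes that the rule names are not reported here.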

Results

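RNA was sequenced from DLD1, a human colorectal cancer cell line of epithelial character, and from 3 lines derived from it. SA was grown out of colonies in soft agar and SPH out of colonospheres, and the labels call both mesenchymal. METS came from a lung metastasis of a xenograft and is labelled epithelial. The series title places the lines along the transition from epithelial to mesenchymal cells and back during metastasis. Each line is represented by 1 library, so a difference between 2 lines has no replicate check. Values are in RPKM, and log2 folds are on the scale of log2(RPKM + 1), which understates the change of genes with low values. Of 57746 genes listed, 11030 reached 1 RPKM in DLD1, 11177 in SA, 11238 in SPH and 10920 in METS. Correlations across genes, which are not independent replicates, ran from 0.970 (SPH with METS) to 0.990 (SA with SPH). At 1 RPKM, a transcript of 1 kb corresponds to about 53.7 reads in DLD1 and 53.1 in SPH, estimated from the step size of the low values, so values under 0.1 RPKM rest on few reads.

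The soft agar line SA was compared with DLD1 to see which genes accompany its mesenchymal label. VIM, the intermediate filament of mesenchymal cells, stood at 12.5 RPKM in SA and 0.18 in DLD1 (log2 fold 3.51). The secreted matrix proteins IGFBP7 and SPARC stood at 6.17 and 5.96 RPKM against 0.12 and 0.19 (2.68 and 2.55). The basal keratin KRT5 (4.96 against 0.13 RPKM, 2.40) and the secreted WNT antagonist DKK4 (4.26 against 0.04 RPKM, 2.34) were also among the 6 genes at least 4-fold higher. The 3 genes at least 4-fold lower were the imprinted long noncoding RNA H19 (9.74 against 58.0 RPKM, -2.46), the intestinal keratin KRT20 (4.06 against 21.9 RPKM, -2.18) and the calcium-binding protein gene S100P (6.78 against 33.1 RPKM, -2.13).

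Next in size in SA were PRF1, known as the perforin gene of cytotoxic lymphocytes, at 4.19 against 0.30 RPKM, just under the 4-fold rule, and the cystatin CST1 at 5.52 against 0.70 RPKM (1.94). CST1 has close copies among the other cystatins of its cluster, so its reads may be shared. On the lower side, EFHD1 stood at 1.72 against 7.89 RPKM (-1.71), the cysteine protease inhibitor CST6 at 0.84 against 4.98 (-1.70), PRR9 at 1.15 against 4.90 (-1.46), C6orf15 at 2.94 against 8.95 (-1.34) and the activin subunit gene INHBB at 3.78 against 11.01 (-1.33). In all, 9 genes of 11367 differed at least 4-fold and 77 at least 2-fold, 50 of them higher and 27 lower. With a pseudocount of 0.1 the 4-fold count was 50, and with 5 it was 2.

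The colonosphere line SPH carried the same genes at much the same levels. VIM stood at 12.2 RPKM (log2 fold 3.48 against DLD1), IGFBP7 at 6.23 (2.69), SPARC at 5.72 (2.498), KRT5 at 5.15 (2.44) and DKK4 at 3.47 (2.10). CST1 reached 6.93 RPKM (2.22), and S100A4, a calcium-binding protein linked to cell motility, stood at 52.4 RPKM in SPH against 8.56 in DLD1 (2.48) and 28.5 in SA. Lower in SPH by at least 4-fold were SH3BGRL (0.12 against 6.16 RPKM, -2.68), the membrane glutathione transferase MGST1 (0.03 against 4.88 RPKM, -2.51), KRT20 (3.18 RPKM, -2.46 against its 21.9 in DLD1), PRR9 (0.11 RPKM, -2.41) and CST6 (0.32 RPKM, -2.18). H19 was lower as well, at 14.7 RPKM (-1.91), as were EFHD1 at 1.25 RPKM (-1.98) and MAGED1 at 2.11 against 9.94 RPKM (-1.81).

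SPH and SA differed little from each other. On the scale of log2(RPKM + 1), SH3BGRL, at 3.82 RPKM in SA and 0.12 in SPH, was the 1 gene of 11431 that differed at least 4-fold. By that scale 30 differed at least 2-fold, 15 in each direction. Low values count little on it, and MGST1, at 2.22 RPKM in SA and 0.03 in SPH, did not reach 4-fold. With a pseudocount of 0.1 the 4-fold count was 13. Against DLD1, SPH had 13 genes at least 4-fold different (8 higher, 5 lower) and 144 at least 2-fold (82 higher, 62 lower). SA and SPH shared 6 higher genes and 1 lower gene at 4-fold and 43 higher and 17 lower genes at 2-fold. Unchanged libraries with the spread seen between SA and SPH, set against 1 shared DLD1 library, gave on average 5.45 shared genes at 2-fold and 0 at 4-fold in 100 simulated draws. SA and SPH are the closest pair (SD of the log2 fold 0.19 over 6301 genes, against 0.29 for DLD1 and METS). The error of the single DLD1 library is unknown, so the simulated numbers may be too low. Independent lists of these sizes would share 0.355 higher and 0.145 lower genes at 2-fold, and part of any excess may come from the shared DLD1 library.

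The labels divide the lines into a mesenchymal class (SA and SPH) and an epithelial class (DLD1 and METS), with 2 lines in each. VIM was higher in the mesenchymal lines by 3.47 ± 0.11 on the log2 scale (SE, adjusted p = 6.3e-04, limma-trend), at 12.5 and 12.2 RPKM against 0.18 and 0.22. IGFBP7 rose by 2.74 ± 0.12 and SPARC by 2.56 ± 0.12 (adjusted p = 0.0013 for each, limma-trend). KRT5 rose by 2.46 ± 0.12 and DKK4 by 2.22 ± 0.13 (adjusted p = 0.0014 and 0.0050, limma-trend). These 5 genes were among the 6 at least 4-fold higher in all 4 pairs of a mesenchymal and an epithelial line, and no gene was at least 4-fold lower in all 4.

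In the class test 40 of 11262 genes passed adjusted p 0.05 (limma-trend), 36 higher and 4 lower in the mesenchymal lines. Among the higher genes were the crosslinking enzyme TGM2 (3.39 and 3.16 RPKM in SA and SPH, 0.29 and 0.15 in DLD1 and METS), the lysyl oxidase family member LOXL4 (2.30 and 2.25 against 0.03 and 0.09), the membrane-cytoskeleton linker MSN (2.23 and 2.18 against 0.11 and 0.04) and the beta-tubulin TUBB2B (3.34 and 4.15 against 0.52 and 0.26). The 4 lower genes were INHBB (log2 fold -1.26), EFHD1 (-1.65), the carbonic anhydrase CA2 (-1.03) and the villin-like gene VILL (-1.23). ALPP, a placental-type alkaline phosphatase with a near-identical copy, and CHAC1, a glutathione-degrading enzyme, stood at -1.42 and -1.27 and did not pass (adjusted p = 0.054 and 0.060, limma-trend). H19 (-4.99) and S100P (-2.92) were the lowest by class fold among the named genes, with adjusted p = 0.48 and 0.24 (limma-trend), with METS and DLD1 far apart.

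The p-values of this test measure the spread between the 2 different lines of a class, not between replicate cultures. Without the SA library 5 genes passed and without SPH 6, without DLD1 305, without METS 27, and with no filter on low values 0 of 24097 genes passed (2208 at an unadjusted p under 0.05, limma-trend).

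**Figure D1:**
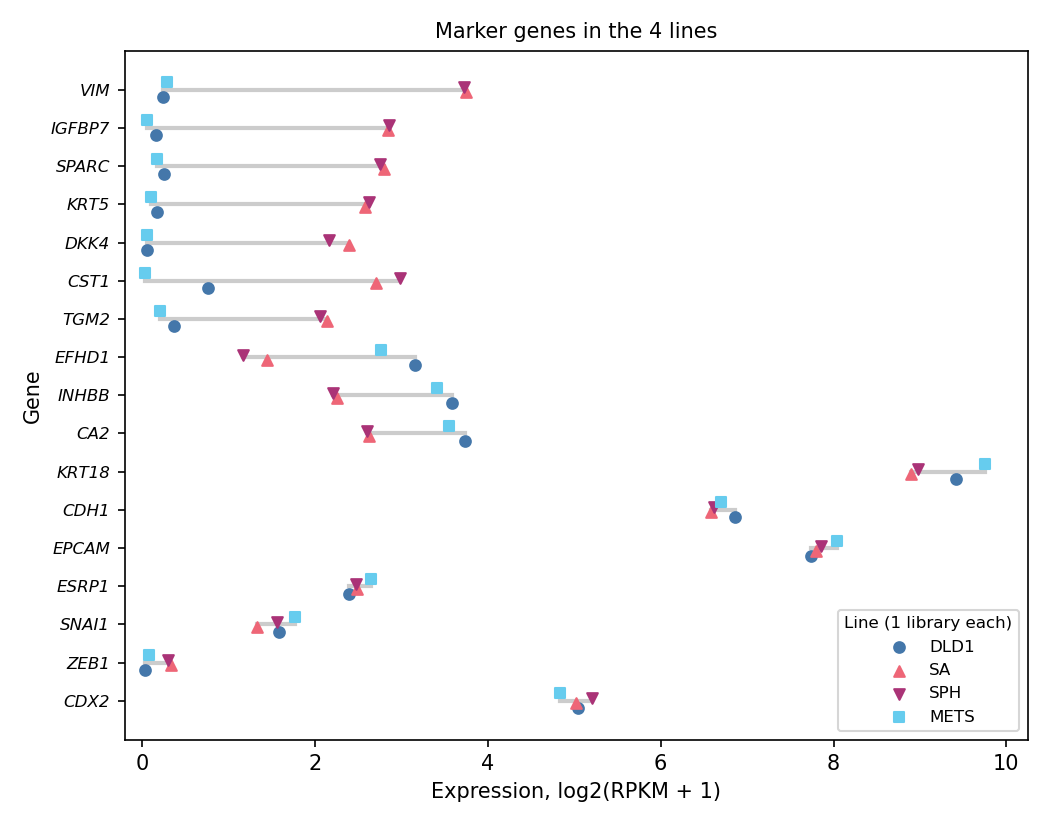
Expression of 17 marker genes in each line as log2(RPKM + 1) on the horizontal axis, with 1 point per line (1 library each) and a grey bar over the range of the 4 lines. VIM, at 12.5 and 12.2 RPKM in SA and SPH and 0.18 and 0.22 in DLD1 and METS, separates the classes, while the points of CDH1, EPCAM and ESRP1 lie close together.

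Epithelial genes stayed high in the mesenchymal lines. E-cadherin, CDH1, stood at 115 RPKM in DLD1, 94.5 in SA, 97.3 in SPH and 103 in METS, and the adhesion molecule EPCAM at 212, 222, 231 and 263 RPKM. The epithelial splicing regulator ESRP1 ranged from 4.24 to 5.28 RPKM. None of the 32 genes of epithelial adhesion and junctions passed the class test, over all genes or adjusted over the list alone. As a group, however, they lay lower in SA (27 of 32 below DLD1, median log2 fold -0.26) and SPH (27 of 32, -0.13), with both medians below the central 95% of 10000 random lists matched on expression. The random lists were not matched on GC content. Most of the 27 lists lay outside that range in SA and many did in SPH, so lying outside it does not set a list apart. The tight junction gene CLDN1 stood at 2.48, 1.36, 0.56 and 1.47 RPKM in DLD1, SA, SPH and METS.

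The keratins KRT8, KRT18 and KRT80 were lower in both mesenchymal lines than in DLD1 and highest in METS. KRT8 stood at 817 RPKM in DLD1, 565 in SA, 587 in SPH and 1084 in METS, KRT18 at 680, 476, 504 and 865, and KRT80 at 40.7, 27.5, 22.7 and 45.5. Of 8 measured keratins 7 were lower than DLD1 in SA and in SPH, with medians of -0.54 and -0.49. KRT5 alone passed the class test over all genes. Adjusted over the list alone, 5 of 7 tested keratins passed, KRT5 higher and 4 lower. Among 16 epithelial transcription and splicing regulators, OVOL1 and GRHL3 were lower and passed adjusted over the list alone, while none passed over all genes (limma-trend). OVOL1 stood at 4.97, 3.31, 3.04 and 5.94 RPKM and GRHL3 at 17.3, 11.9, 11.5 and 15.8 in DLD1, SA, SPH and METS.

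Mesenchymal markers moved in part. Of 31 listed genes 13 reached 1 RPKM in a line, and VIM, SPARC, MSN and the receptor tyrosine kinase AXL passed the class test (4 over all genes and 4 adjusted over the list alone, all higher). AXL stood at 1.90 and 1.5 RPKM in SA and SPH against 0.28 and 0.15 (log2 fold 1.15, adjusted p = 0.0497, limma-trend). The list median was 0.31 in SA and 0.30 in SPH, above the range of random lists. VIM, SPARC, MSN and AXL were under 1 RPKM in DLD1 and METS and entered the list only through SA and SPH. The filter thus raised that median, and it is no separate evidence of a rise of the group. The transcription factors that drive epithelial-mesenchymal transition were low or flat, and ZEB1, though low, was higher in SA and SPH. ZEB1 stood at 0.26 and 0.23 RPKM in SA and SPH against 0.02 in DLD1 and 0.06 in METS. That is 13 and 11.5 times the value of DLD1, but it lay under the minimum of 1 RPKM and was not tested. ZEB2 is listed at 0 in all 4 lines, SNAI2 did not exceed 0.05 RPKM nor TWIST1 0.02, and SNAI1 lay between 1.52 and 2.41 RPKM. Of the 5 factors that reached 1 RPKM none passed the class test, and SOX4 had the largest class fold (0.35).

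The median of the WNT pathway targets was higher in the mesenchymal lines, but several targets did not follow. Their median was 0.23 in SA and 0.19 in SPH, above the range of random lists. Of 21 genes 11 were higher in all 4 pairs and 1 was lower. AXIN2 stood at 104, 122, 95.2 and 116 RPKM in DLD1, SA, SPH and METS, and ASCL2, CCND1 and SOX9 were highest in METS. DKK4, APCDD1 and NOTUM, each of which encodes a WNT antagonist, passed over all genes, and 5 passed adjusted over the list alone (all higher, limma-trend). APCDD1 stood at 3.06 and 2.59 RPKM against 0.27 and 0.38, and NOTUM at 2.22 and 2.57 against 0.65 and 0.48. DKK4, APCDD1 and NOTUM stayed under 1 RPKM in DLD1 and METS, so they entered the list through SA and SPH alone, which raises its median. LGR5, a stem cell receptor, stood at 8.73, 8.53, 7.72 and 4.94 RPKM in DLD1, SA, SPH and METS, and MYC at 47.2, 54.5, 57.2 and 61.8. Of 20 genes in the TGF-beta response list GDF15 was lower and passed adjusted over the list alone (limma-trend), at 28.6 and 28.9 RPKM against 50.6 and 97.0. GDF15 is also on the list of p53 targets, and adjusted over that list alone it did not pass.

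Several metabolic and stress groups were slightly lower in SA and SPH. Cholesterol and fatty acid synthesis had medians of -0.24 and -0.25, with 19 of 24 genes below DLD1 in each, among them HMGCS1 (83.1 RPKM in DLD1, 66.3 in SA, 62.5 in SPH) and SQLE (29.9, 26.6 and 22.0). The unfolded protein and amino acid stress list had medians of -0.15 and -0.24. Adjusted over that list alone 6 genes passed (limma-trend), 5 lower, including CHAC1, ATF3 and the asparagine synthetase ASNS (37.6, 25.6, 24.3 and 48.6 RPKM in DLD1, SA, SPH and METS), and STC2 higher. STC2 was the 1 gene that passed over all genes, and it is listed at 0 in DLD1 and METS against 1.59 and 1.55 RPKM in SA and SPH. Chemokines and inflammatory cytokines had medians of -0.21 and -0.26, and the cytokine gene LIF and the chemokine gene CXCL5 passed adjusted over the list alone, while none passed over all genes.

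Intestinal genes moved in different directions. KRT20 was lower in all 3 derived lines, MUC13 stood at 8.34, 9.27, 12.11 and 1.74 RPKM in DLD1, SA, SPH and METS, and PHGR1 was highest in METS (6.48 RPKM against 0.12 in DLD1). The intestinal transcription factor CDX2 stood at 31.9, 31.4, 36.0 and 27.6 RPKM in the same order, and of 13 measured intestinal genes CA2 alone passed the class test, over all genes and adjusted over the list alone (limma-trend). The list median was 0.17 in SPH, above the range of random lists, and 0.00 in SA, within it. Of 7 stem cell and colonosphere markers none passed, with medians of -0.04 in SA and -0.15 in SPH, both inside the range, and of 0.23 in METS, above it, which turned to -0.20 with a minimum of 5 RPKM. Among proteases and their inhibitors ADAM19 (1.18 and 1.17 RPKM in SA and SPH against 0.05 and 0.13) passed adjusted over the list alone. Among receptor tyrosine kinases and ligands AXL passed over all genes and 4 adjusted over the list alone, 2 higher and 2 lower. FGFR3 was among the lower (0.74 and 0.34 RPKM against 1.72 and 3.41). The long noncoding RNA PVT1 stood at 2.62 and 2.48 against 1.16 and 1.12 RPKM and was the 1 member of its list that passed adjusted over the list alone. No gene of the lists of p53 targets, interferon response, hypoxia and glycolysis, the NOTCH pathway, drug transport, DNA methylation and Polycomb machinery or mitochondrial transcripts passed the class test on either count (limma-trend).

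METS was compared with DLD1 to describe the line that came back from the lung of the host. H19 stood at 2893 RPKM in METS against 58.0 in DLD1 (log2 fold 5.62). S100A4 reached 305 against 8.56 RPKM (5.00), KLHL4, of the kelch-like family, 48.4 against 2.27 (3.92), and the intestinal gene PHGR1 6.48 against 0.12 (2.74). The cell cycle inhibitor CDKN1C, which is imprinted like H19, stood at 13.1 against 2.27 RPKM (2.11), the chloride channel family gene CLIC3 at 11.9 against 2.13 (2.05) and S100P at 129 against 33.1 (1.93). MEGT1 stood at 7.51 against 0.85 RPKM (2.20), but it overlaps LY6G6D (7.66 against 1.66 RPKM, named after its values were seen), and the reads of the pair cannot be told apart here.

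Among the genes lower in METS, KRT20 stood at 0.50 against 21.9 RPKM (-3.93) and the secreted olfactomedin-like protein gene OLFML3 at 1.40 against 19.4 (-3.09). PBDC1 stood at 0.36 against 8.45 RPKM (-2.80), the matrix protein tenascin, TNC, at 0.08 against 5.55 (-2.60), the extracellular glutathione peroxidase GPX3 at 0.05 against 3.70 (-2.16) and the sulfate-activating enzyme PAPSS2 at 8.22 against 36.1 (-2.01). UGT1A6, a glucuronosyltransferase that shares exons with the rest of its locus, is listed at 0 in METS against 4.17 RPKM in DLD1. The glucose transporter SLC2A3 followed at 1.31 against 7.72 RPKM (-1.92). Of 11275 genes 14 differed at least 4-fold, 7 in each direction, and 160 at least 2-fold, 59 higher and 101 lower. The 4-fold count was 68 with a pseudocount of 0.1 and 4 with a pseudocount of 5.

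Gene groups that contact the matrix were lower in METS. All 9 measured integrins were below DLD1 (median -0.48), among them ITGA6 (20.2 against 41.1 RPKM) and ITGB6 (0.10 against 1.92). Of 13 collagen and basement membrane genes 11 were below DLD1 (median -0.39), and of 17 YAP and TAZ targets 13 (median -0.35), including CTGF at 3.38 against 9.26 RPKM and NT5E at 10.8 against 29.4. The 26 proliferation genes were all lower (median -0.33), for example MKI67 at 23.1 against 31.3 RPKM, whereas their medians in SA and SPH lay within the range of random lists. Antigen presentation had a median of -0.30, with the immunoproteasome subunits PSMB8 at 9.60 against 20.01 RPKM and PSMB9 at 0.76 against 2.77. The medians of these 5 lists and of mesenchymal markers (-0.25) lay below the central 95% of random lists. Of the 13 mesenchymal markers 11 were below DLD1 in METS, but S100A4, also on that list, stood at 305 against 8.56 RPKM. Those of the TGF-beta response (0.17), long noncoding RNAs (0.15), drug transport (0.12), receptor tyrosine kinases and ligands (0.09) and p53 targets (0.09) lay above it in METS, as did that of stem cell markers. Long noncoding RNAs lay above the range in SA (0.143) and SPH (0.145) as well, and drug transport in SA (0.162). Smaller falls below the range were seen in the mesenchymal lines too, for integrins in SA (-0.15) and SPH (-0.22), collagens in SA (-0.14), antigen presentation in SA (-0.21) and YAP and TAZ targets in SPH (-0.12). Junction genes did not move as a group in METS (median -0.04, inside that range), although the desmocollin DSC2 stood at 6.97 against 1.14 RPKM and the plakophilin PKP2 at 11.1 against 27.1.

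Fibroblast markers were near 0, while ENO2, EGFL7 and a few other markers of further cell types were expressed. The highest of 13 fibroblast markers was 0.18 RPKM in METS, 0.11 in SA, 0.34 in SPH and 0.12 in DLD1. The lung epithelial list reached at most 1 RPKM in METS (NKX2-1, at 0.57 in DLD1), and the immune list 1.36 RPKM in METS (CD14, at 0.89 in DLD1). Endothelial markers reached 3.63 RPKM (EGFL7 in SPH, at 2.33 in DLD1) and neuronal markers 8.21 RPKM (ENO2 in METS, at 5.51 in DLD1). The melanocyte, liver and squamous list reached 5.15 RPKM (KRT5 in SPH), and of its 2 other members at 1 RPKM or more, both melanocyte markers, MITF was the higher (2.87 RPKM in DLD1). None of 24 matched cancer testis antigens exceeded 0.06 RPKM.

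**Figure D2:**
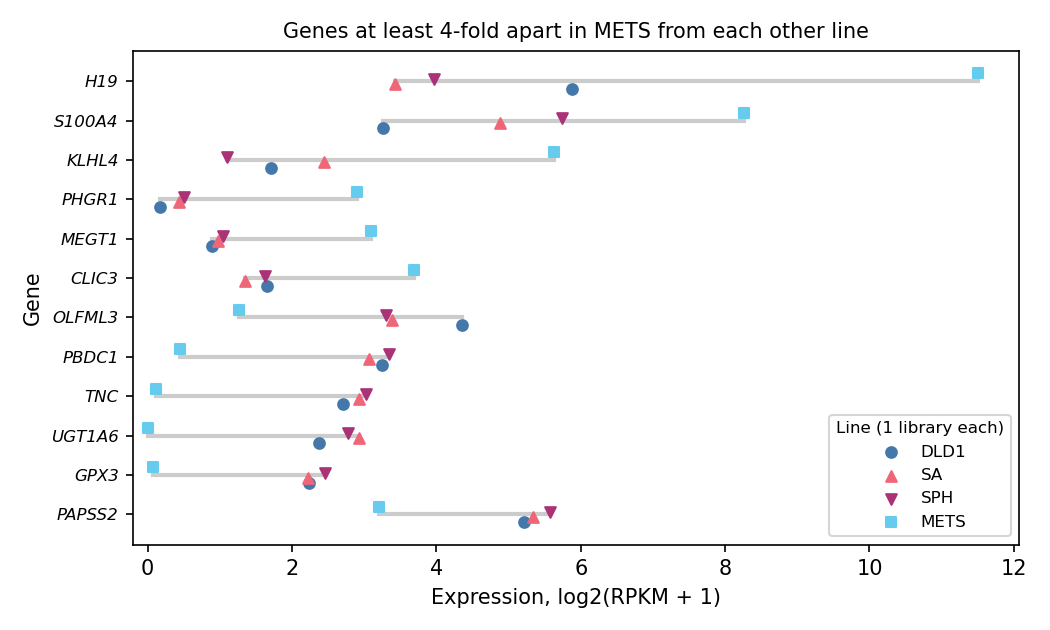
Expression of the 12 named genes at least 4-fold apart in METS from each of the other lines, as log2(RPKM + 1) on the horizontal axis, with 1 point per line (1 library each) and a grey bar over the range. The 6 upper genes, led by H19 at 2893 RPKM, have their highest point in METS, and the 6 lower genes their lowest.

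METS was also set against the mesenchymal lines, to see which genes part a line labelled epithelial from both of them. S100A4 (305 RPKM against 28.5 in SA and 52.4 in SPH), H19, KLHL4, PHGR1, CLIC3, MEGT1, LY6G6D, S100P and C6orf15 were at least 4-fold higher than in both. VIM, SPARC, IGFBP7, KRT5, DKK4 and CST1 were among the genes at least 4-fold lower, together with TNC, GPX3, PAPSS2, OLFML3, PBDC1, UGT1A6 and CRABP2, a retinoic acid-binding protein gene outside the naming rule (1.81 RPKM against 19.7 and 20.5). The totals were 9 higher and 14 lower genes, and 6 higher and 6 lower genes were apart from DLD1 as well.

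The genes changed in both mesenchymal lines were then followed into METS. Of 7 genes changed at least 4-fold in both SA and SPH, 6 lay within 2-fold of DLD1 in METS on the scale of log2(RPKM + 1), among them VIM, IGFBP7, SPARC, KRT5 and DKK4. KRT20 was the exception, and stood lower still in METS. On that scale any 2 values under 1 RPKM lie within 2-fold. The 5 genes named first were under 1 RPKM in both DLD1 and METS, so their return means low values in both. IGFBP7, for example, stood at 0.12 RPKM in DLD1 and 0.04 in METS. At 2-fold, 46 of 60 genes lay within 2-fold of DLD1 in METS and 11 kept their change. Taking METS as the base instead, 23 genes were at least 4-fold different in both mesenchymal lines, and 7 of them lay within 2-fold of METS in DLD1. The count of 6 became 33 with a pseudocount of 0.1 and 1 with a pseudocount of 5.

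**Figure D3:**
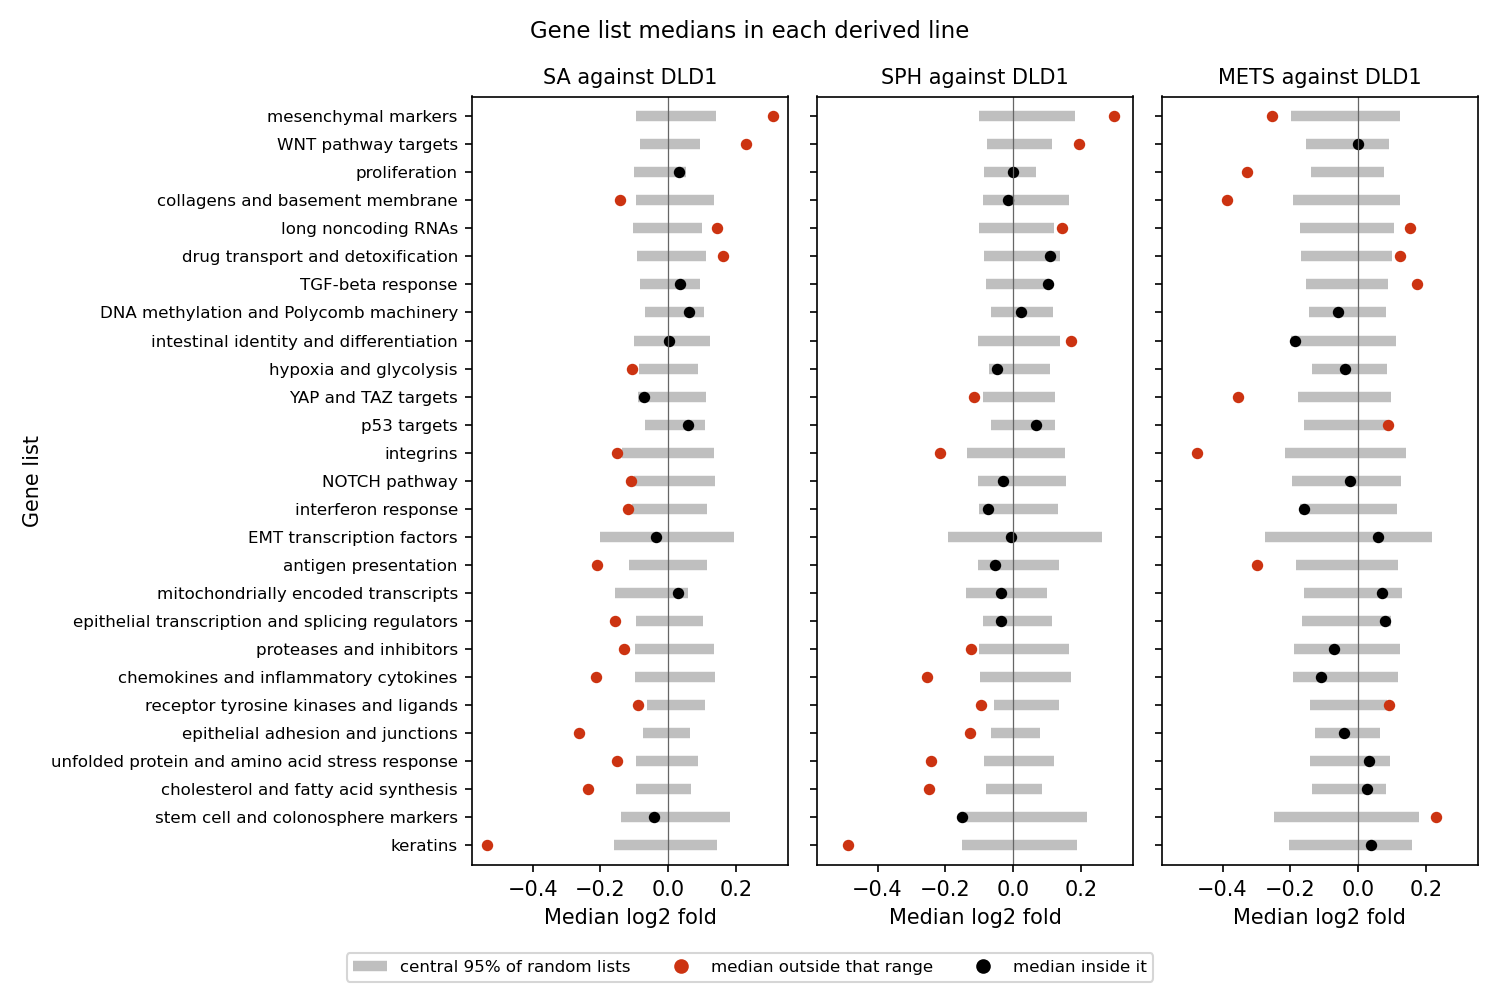
Median log2 fold of 27 gene lists in SA, SPH and METS against DLD1 (horizontal axis, 1 library per line), with the central 95% of 10000 random lists of matched expression as grey bars and medians outside that range in red. Mesenchymal markers (0.31 in SA, 0.30 in SPH) and keratins (-0.54 and -0.49) lie outside in both mesenchymal lines, and integrins are lowest in METS (-0.48). Some mesenchymal markers entered their list only through SA and SPH, which raises its median there.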

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

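The tests weighed here were chosen after the results were seen. H19, S100P and C6orf15 moved one way in both mesenchymal lines and the opposite way in METS, each by at least 2-fold against DLD1, and with 1 library per line the difference was not tested. H19 was lower in SA and SPH (log2 folds -2.46 and -1.91) and higher in METS (5.62), a difference of 7.80 between METS and the mean of SA and SPH. S100P differed by 3.89 (-2.13 and -1.77 against 1.93). C6orf15 differed by 2.33 (-1.34 and -1.29 against 1.01), at 8.95, 2.94, 3.06 and 19.1 RPKM in DLD1, SA, SPH and METS.

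Cells of the xenograft host were considered for the genes far higher in METS, among them H19, S100A4, KLHL4 and PHGR1. The 55 markers of fibroblasts, endothelium, immune cells and lung epithelium had a median of 0.01 RPKM in METS. The 5 markers above 0.648 RPKM in METS, 0.1 of the level of PHGR1 (CLDN5, EGFL7, CD14, NKX2-1 and AGER), were at 0.57 RPKM or more in DLD1 too. The largest rise from DLD1 to METS among the 55 was 0.47 RPKM (CD14), against 6.36 for PHGR1. A xenograft host is of another species, and the genome build was the human hg19. Human marker genes may then miss host reads, so these values cannot decide on host cells. The deposited values held no shift of the whole METS library, as the median log2 fold of all 11275 genes against DLD1 was -0.029 (SD 0.32 over genes). Scaling to library size keeps this median near 0 in advance, so it is no test of a cause. Reciprocal expression of H19 and its imprinted neighbour IGF2 held in 1 of 3 derived lines, since IGF2 was lower in SA, SPH and METS alike (1.58 RPKM in DLD1, then 0.53, 0.49 and 0.61) while H19 was lower in SA and SPH. A change in METS acquired in the host, or a rare DLD1 clone picked out by the passage, remains open and was not tested.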

How the results depend on the processing

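The correction for GC content was chosen after seeing the data, and the other settings before. Counts by size depend on the pseudocount, because many changed genes have low values. With a pseudocount of 0.1 the genes at least 4-fold different numbered 50 in SA, 80 in SPH and 68 in METS against DLD1, 13 in SPH against SA, 107 in METS against both, 32 in all 4 class pairs and 33 back within 2-fold of DLD1 in METS. With a pseudocount of 5 these counts were 2, 2, 4, 0, 5, 1 and 1. The 2-fold rule gave 77, 144, 160, 30, 167, 39 and 46, and the 8-fold rule 2, 2, 5, 0, 5, 2 and 2. A minimum of 5 RPKM left 0 genes between SPH and SA. Dropping the filter and median-of-ratios factors kept every count by size within 1.5 times.

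The class test (limma-trend) called 40 genes, 26 with a pseudocount of 0.1, 35 with 5, 45 with median-of-ratios factors and 42 without trend. With no filter it called 0, and with a minimum of 5 RPKM in 2 libraries 5, all among the 40, where 6990 genes were tested. Corrected for GC content it called 26, all among the 40. Leaving out 1 library gave from 5 (without SA) to 305 (without DLD1) genes, with the lone line of a class assumed to vary like the others. The cause of these changes was not tested.

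The number of lists with a class median outside the central range was 12 under every setting run. The GC correction was not run on the lists, and the random lists were not matched on GC content. In the class test the central 95% of that correction spanned 0.163 in DLD1, 0.080 in SA, 0.085 in SPH and 0.165 in METS on the log2 scale. Small list medians may therefore hold a part from GC content, which was not tested. Under a minimum of 5 RPKM the median of proteases and inhibitors in SPH went from -0.13 to 0.15, and that of stem cell markers in METS from 0.23 to -0.20, since fewer members entered. Of 136 class folds of named genes, 5 lost their call with a pseudocount of 0.1 and 3 gained one with median-of-ratios factors. Of 48 line folds of named genes, 39 moved by more than 0.21 (the SD of SPH against SA over all genes) with a pseudocount of 0.1, and none changed sign. Depth limits values under 0.1 RPKM most.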

Other observations

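The tests in this part were chosen after the results were seen, as were the genes of this paragraph. The retinol receptor STRA6 stood at 1.39 RPKM in SA and 1.29 in SPH, against 0.01 or less in DLD1 and METS. CRABP2 stood at 9.59 RPKM in DLD1, 19.7 in SA, 20.5 in SPH and 1.81 in METS. ALDH1A1, a retinaldehyde dehydrogenase also used as a stem cell marker, stood at 2.78 RPKM in METS and at most 0.03 in the other lines. TIMP3, a metalloproteinase inhibitor, stood at 1.26, 0.73, 0.06 and 4.97 RPKM in DLD1, SA, SPH and METS. The intestinal mucin MUC13 and the chloride channel CFTR stood at 8.34 and 3.27 RPKM in DLD1 and at 1.74 and 0.44 in METS.

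Genes of the X chromosome made up 12 of 143 genes at least 2-fold different in METS among the 9891 tested genes that could be given a chromosome, which is 3.95% of 304 X genes against 1.37% elsewhere (Fisher's exact test, two-sided, p = 0.0015, adjusted p = 0.10 over 69 tests of chromosomes and lines). It does not pass the correction. Of the 12, 9 were lower, including PBDC1, MAGED1 and NOX1, and 3 higher, KLHL4, SH3BGRL and PLXNB3.

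A set of 34 genes stood at most at 0.1 RPKM in DLD1 and METS and at 0.5 or more in both SA and SPH, against 1 gene with the opposite pattern. It includes DKK4, LOXL4, STC2 and broadly expressed genes such as the fatty acid elongase ELOVL5 (1.51 and 1.21 RPKM). It also holds the T cell receptor gene TRBC2 (0.90 and 0.75 RPKM), and the T cell kinase ZAP70 (0.33 and 0.49 RPKM, listed at 0 in DLD1 and METS) and PRF1 (4.19 and 3.65 RPKM against 0.30 and 0.86) were higher in the same lines, while the leukocyte genes PTPRC, CD3D and CD3E are listed at 0 in all 4. Over the 34 genes the log2 ratio of SPH to SA had an SD of 0.20, against a median of 0.37 for 10000 random sets (percentile 0.01). The random sets were matched on level and held to the same minimum of 0.5 RPKM in both lines. They were not matched on gene length, which sets the reads behind a value, so their wider spread may be counting error. Over 6301 genes of at least 5 RPKM in all lines that SD was 0.19, so 0.20 is not unusual for this pair of lines. Fibroblasts are argued against by the fibroblast markers, at most 0.34 RPKM in SA or SPH against 12.2 or more for VIM. The GC content of transcripts is argued against as the whole source of the class folds, for the 37 of 40 called genes with a GC value, whose median absolute fold was 1.36 before and 1.33 after the correction, with median SEs of 0.12. After it 26 were still called. The 11 that lost their call had adjusted p of 0.031 to 0.0497 before and 0.052 to 0.16 after (limma-trend), with the median fold going from 1.22 to 1.18 and the median SE from 0.124 to 0.128, so they lay near the threshold from the start. The 3 genes without a GC value, left uncorrected, lost their call as well. Dilution by cells without epithelial junctions would lower the junction genes as much as the 6 genes at least 2-fold lower in all 4 class pairs, but the 32 junction genes, listed before the data were seen, had a median log2 fold of -0.26 in SA (SD 0.28) and -0.13 in SPH (SD 0.27). Dilution by cells that carry junctions stays open. As far as the ratio is even, a small population of other cells at a like share in SA and SPH may explain it. A state shared by both mesenchymal lines, as the labels give it, would do so equally. Bulk libraries leave both open.

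A few genes were all but lost in METS. The 5 genes at 2 RPKM or more in DLD1 and at 0.1 or less in METS included GPX3, TNC, UGT1A6 and the pseudogene ST13P6, whose reads may be shared with its parent gene. Loss of DNA reaching the nearest expressed genes is argued against, since the lowest fold among 10 such neighbours was -0.56 (HJURP, beside UGT1A6) and their median -0.08. A smaller deletion or silencing of single genes could still be the source, and expression values do not separate them. MGST1 was lost in SPH in the same way, at 0.03 RPKM against 4.88 in DLD1 and 2.22 in SA.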
